A study of Arabidopsis thaliana with 12 samples.

How the data were processed

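The data are 12 arrays of total RNA from Arabidopsis thaliana, 6 of WT and 6 of the toc75 mutant, both of the Columbia ecotype per the labels. The deposited values are relative intensities on a linear scale, 1 per feature and array. How the authors made these intensity values (labelling, background correction, scaling) is not given in the sources used here, nor is the tissue, growth stage or array build. The deposited columns have means between 0.933 and 1.04, so the values look scaled to each array's own mean, which stays an inference. Exact zeros are present, and 43 features were at 0 on all arrays. In 3 features the values reach a ceiling near 100, so their highest values are lower bounds; none is named. No background or detection value was used here, so the number of arrays and the floor limit the precision. No 2 arrays held identical values.

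Groups and array numbers were taken from the labels. The main tests, 20 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined; 4 further lists, some alternatives and some tests of explanations were chosen later. Array medians differed by 1.62-fold, beyond the 10% within which the values would have been used as deposited, so the arrays were quantile normalized with limma 3.58.1 in R 4.3.3. After scaling, values below the 5th percentile of all positive values (0.0719, or -3.80 on the log2 scale) were lifted to it before log2 was taken. The written plan named only values at or below 0, which would have placed zeros above small positive values; that reading was run as an alternative. The floor held 97 features on all arrays, and 2556 features were above it on all arrays. A fold change of a feature near the floor depends on the floor, on the scaling and on how zeros are treated, so it can be understated or overstated. Features needed a value on at least 4 arrays of each group.

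Features were named through the platform annotation and updated through gene identifiers to a table of TAIR10.1 genes, from which no coordinates were used. Of 3439 features, 692 had a single gene, 690 of which matched, giving 689 loci; 870 had several genes and were not named; 1877 had none in the annotation used. AT2G25870 was on 2 features that disagreed, with log2 fold changes of -1.03 and 0.07, neither past the threshold.

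Each feature was fitted with lmFit and eBayes, two-sided, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Named were every measured TOC75 family gene; the 12 largest rises and 12 largest falls among calls whose 6 toc75 arrays all lay on the same side of the WT mean; and up to 4 members of each list with the smallest p, whether or not they passed. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. A further 4 lists were chosen from the names of measured genes once these were known, before any fold change was computed. Array medians were compared with an exact permutation test. Intervals are 95%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

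The labels give both groups the numbers 1 to 6. Same-numbered arrays deviated together from their group means, with correlations across features of 0.42, 0.41, 0.28, 0.31, 0.44 and 0.45, and each array correlated best with its own number in the other group. All are over 0.1, so the numbers were taken to pair the arrays. The main fit and its adjusted p-values do not use this pairing, and the array number as a block was run as an alternative. This pairing comes from the values; the labels do not say what a number marks.

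Alternatives covered scaling, low values, a filter on dim features, the variance model, array weights, the replicate block, averaged or correlated array numbers, thresholds and each array left out in turn. Those added after seeing the data were the other reading of the floor, a constant added per array, features above the floor only, subsets of array numbers, and averaging combined with the block.

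The fit was tested on simulated data with 3439 features and 200 changed ones. Feature means were those of WT, each spread was pooled over both groups, and same-numbered arrays shared part of it. The fit recovered 25.4% of changes of 0.5, 64.2% of changes of 1 and 81.8% of changes of 2 on the log2 scale, with 0 false calls among 114. The simulation held no intensity gap between groups, no larger toc75 scatter and no link between consecutive numbers. Its false calls therefore do not show how many the real data could give.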

Results

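Total RNA of Arabidopsis thaliana plants of the Columbia ecotype was measured on 12 arrays. Of these, 6 arrays held wild-type (WT) RNA and 6 held RNA of the toc75 mutant, which the labels describe as affected in the passage of proteins into the chloroplast. TOC75 is the name of the channel protein of the outer chloroplast envelope, and the labels do not say which TOC75 gene carries the mutation. Each array gave a relative intensity for 3439 features. A single gene was named for 690 of them, 870 carried several genes, and 1877 had no gene in the annotation used. Nothing in the labels says whether the 6 arrays of a group came from separate plants, so p-values measure the spread between arrays, which may be technical.

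The toc75 arrays had lower deposited intensities over most of their features. The median relative intensity was 0.502 ± 0.018 (SD, n = 6) on WT arrays and 0.350 ± 0.026 (SD, n = 6) on toc75 arrays. This gap of -0.52 on the log2 scale had p = 0.0022 in a two-sided exact permutation test, the smallest value that 924 splits of the arrays can give. The test takes the arrays as independent and does not use their numbers. Within the 6 same-number pairs the gap ran from -0.44 to -0.60. On average 186.5 features were at 0 on a WT array and 291.7 on a toc75 array. The 10 brightest features held 14.6% of the summed intensity on WT arrays and 18.9% on toc75 arrays. Fold changes below are therefore relative to intensity distributions made equal by quantile normalization.

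**Figure D1:**
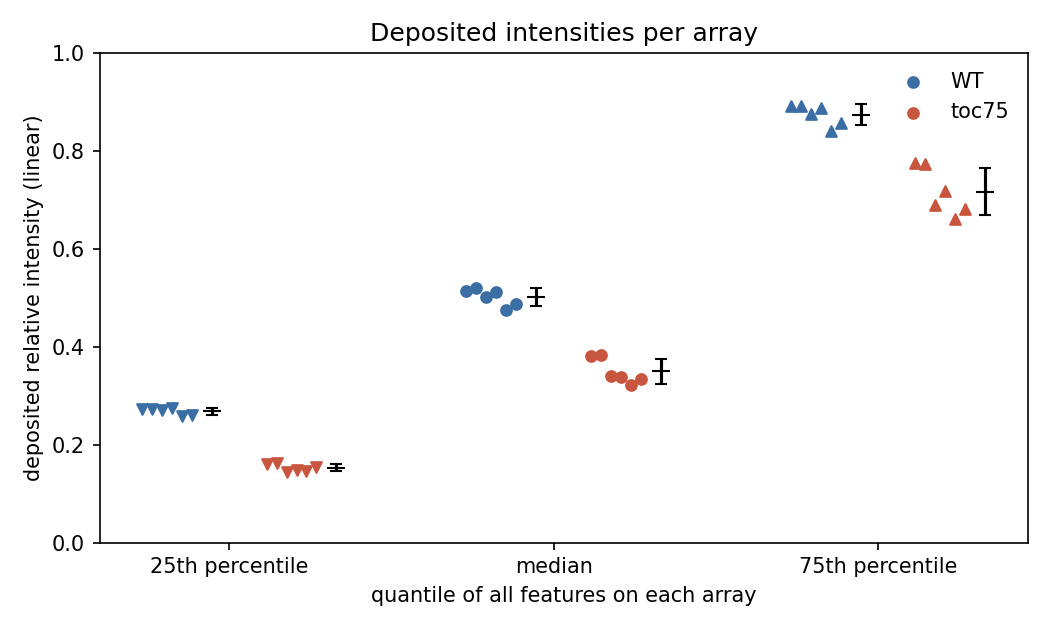
Deposited relative intensity (linear, y axis) at the 25th percentile, median and 75th percentile of the 3439 features on each array (x axis); each symbol is 1 array, and black bars give the mean ± SD of 6 arrays. The 6 toc75 medians lie between 0.321 and 0.383, below the WT medians of 0.475 to 0.520.

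The first question was which genes differ in transcript level between toc75 and WT plants. The largest rise among single-gene features was that of AT3G52070, with a log2 fold change of 1.51 ± 0.11 (SE, n = 6 per group), or 2.84-fold. AT3G56250 rose by 1.49 ± 0.19, AT4G33760 by 1.38 ± 0.22 and AT4G16590 (CSLA01, a cellulose synthase-like protein) by 1.31 ± 0.21 on the same scale. AT1G24040, AT4G24840, AT4G27510 and AT1G17850 rose between 2.26-fold and 2.46-fold. AT3G11960, AT1G49850, AT4G16410 and AT3G04650 completed the 12 largest rises, which were 2.05-fold, 2.02-fold, 2.02-fold and 2.01-fold higher in toc75. The limma adjusted p-values of the 12 genes ran from 5.74e-06 for AT3G52070 and AT4G16410 to 0.026 for AT1G17850. The calls of AT3G52070, AT4G16410 and AT3G04650 held under every setting that measured them except consecutive array numbers averaged with a block (adjusted p = 0.051). With the values as deposited 6 of the 12 rises lost their call, at log2 fold changes of 0.49 for AT3G56250, 0.56 for CSLA01, 0.40 for AT4G24840, 0.30 for AT4G27510, 0.25 for AT1G17850 and 0.11 for AT3G11960, with adjusted p of 0.078 to 0.704. AT4G33760 and AT4G16410 were still called there, at 0.80 and 0.60. AT1G17850 also lost its call with each array centred on its median (0.77, adjusted p = 0.116), with cyclic loess (adjusted p = 0.088), with a pseudocount (0.52, adjusted p = 0.065), and without WT replicate 4 (adjusted p = 0.054) or WT replicate 6 (adjusted p = 0.055). AT3G11960 lay at the floor on 5 of the 6 WT arrays, so its fold change is set in part by the floor, and it was at 0.64 when centred, 0.47 with cyclic loess (adjusted p = 0.121) and 0.60 without numbers 5 and 6 (adjusted p = 0.137). With 2 arrays per group, CSLA01, AT4G27510 and AT1G17850 were at 0.71, 0.77 and 0.57 for numbers 5 and 6 alone, AT1G17850 at 1.95 for numbers 3 and 4 alone, and AT3G11960 at 0.58 and 0.63 for numbers 3 and 4 and numbers 1 and 2 alone, none of which passed.

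The largest fall was that of AT1G24240, which was 4.59-fold lower in toc75, with an SE of 0.61 on the log2 scale (n = 6 per group). AT1G22040 fell by 1.56 ± 0.52 on that scale, and AT2G43430 (GLX2-1) fell by 1.47 ± 0.25. AT4G37420, AT2G28790 and AT3G06570 were 2.72-fold, 2.46-fold and 2.43-fold lower. AT4G26900 (AT-HF, an enzyme of histidine synthesis) fell by 1.11 ± 0.22 and AT4G35660, the brightest of the 24 genes in WT, by 1.09 ± 0.15. AT1G76050, AT2G46190, AT2G46050 and AT3G17950 fell by between 1.07 and 1.19. On at least 1 toc75 array 8 of these 12 genes lay at the floor, so their measured fall depends on how such low values are treated. With zeros missing, the falls of AT1G24240 and AT1G22040 were smaller, as given below. The limma adjusted p-values ran from 0.00035 for AT4G35660 to 0.048 for AT1G22040. With each array centred on its median, AT4G35660 lost its call, at -0.36 (adjusted p = 0.082). With zeros missing, AT1G24240 lost its call at -1.82 (adjusted p = 0.054), and AT1G22040 was at -0.74. AT1G22040 and AT3G17950 did not pass with cyclic loess (adjusted p = 0.056 and 0.063), nor AT3G17950 with the array number as a block (adjusted p = 0.059). Without toc75 numbers 3 and 4, AT1G24240, AT1G22040 and AT3G17950 did not pass (adjusted p = 0.084, 0.069 and 0.128), nor AT3G17950 without numbers 5 and 6 (adjusted p = 0.108). AT2G28790, AT3G06570, AT1G76050, AT2G46190 and AT3G17950 lay between -2.03 and -1.74 as deposited. With a constant added per array, GLX2-1, AT4G37420, AT2G28790, AT3G06570 and AT3G17950 lay between -0.97 and -0.59. For numbers 1 and 2 alone, AT1G24240 was at -3.71, with both toc75 arrays at a deposited value of 0, AT1G22040 at -2.87 and AT4G26900 at -0.52. For numbers 5 and 6 alone, AT1G24240 was at -0.78 (adjusted p = 0.690), AT1G22040 at -0.58 and AT1G76050 at -0.66. A pseudocount, which compresses low values, shrank 7 of the rises and 9 of the falls by over 1.5 times. The calls of AT1G22040 and AT3G17950 were also lost in 10 and 9 of the 12 fits that left out 1 array, with adjusted p of up to 0.087 and 0.083. AT1G76050 lost its call without toc75 replicate 1 (adjusted p = 0.052) or WT replicate 6 (adjusted p = 0.051).

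**Figure D2:**
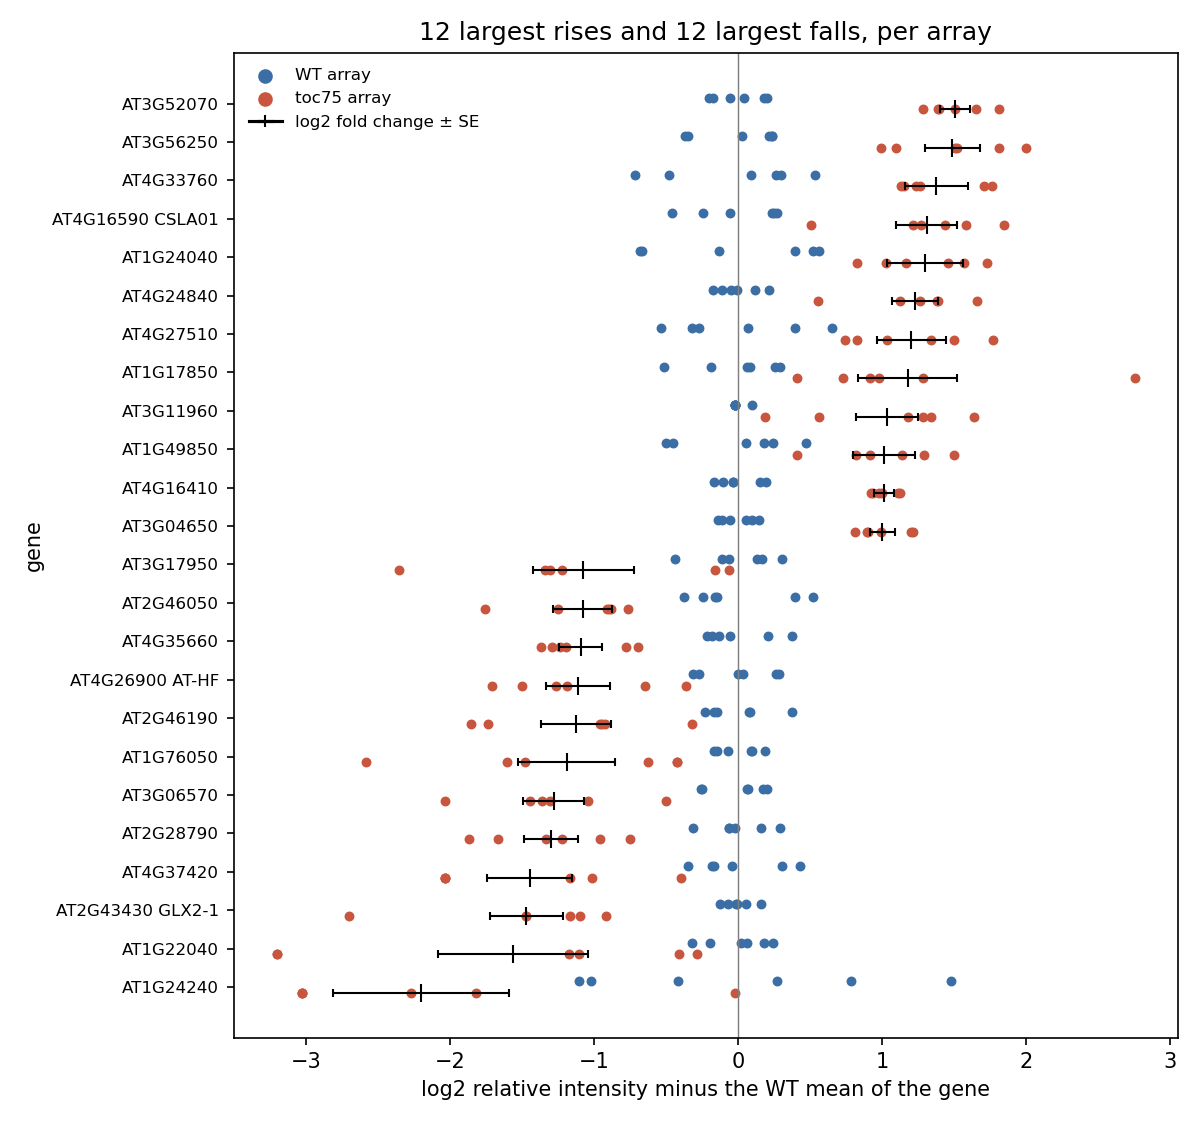
Log2 relative intensity of each array minus the WT mean of the gene (x axis) for the 12 largest rises and 12 largest falls (y axis); blue points are WT arrays, red points are toc75 arrays, and the black mark is the log2 fold change ± SE with 6 arrays per group. AT3G52070 lies 1.51 above the WT mean, and in AT1G24240 the WT arrays themselves have an SD of 1.03.

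Over all features, 884 of 3439 (25.7%) differed between toc75 and WT at an adjusted p under 0.05 in limma, 451 higher and 433 lower in toc75. Among features with a single named gene 187 differed, 101 higher and 86 lower. The median change of the 884 was 1.57-fold, and 152 changed at least 2-fold, of which 63 were higher and 89 lower. In 524 features (15.2%) the 6 toc75 values did not overlap the 6 WT values, where chance gives 0.216% for 12 independent arrays. That chance share would be larger if consecutive numbers held repeats of the same sample. The direction split depended on the scaling: 180 features were higher and 1415 lower with the values as deposited, 914 higher and 404 lower with each array centred on its median, and 952 higher and 418 lower with a constant added per array. These scalings moved the median log2 fold change of all features to -0.41, 0.11 and 0.10. Averaging arrays 1 and 2, 3 and 4, and 5 and 6 within each group left 325 calls. Adding the averaged number as a block left 0 in limma, with 1215 features at an unadjusted p under 0.05 and a lowest adjusted p of 0.051. In the main fit 1280 features had such an unadjusted p. The averages with a block leave few degrees of freedom, so the 0 does not show that the changes are absent. Of 33 named genes that passed, averaging with the block ended the call of all 33, and averaging alone that of 19. Among the largest rises these were AT4G33760, AT1G24040, AT4G27510, AT1G17850 and AT1G49850 (adjusted p of 0.060 to 0.101), and among the largest falls AT1G24240, AT1G22040, AT4G37420, AT1G76050, AT4G26900 and AT2G46050 (adjusted p of 0.054 to 0.265). Consecutive numbers as a random block ended 12 of the 33, with AT1G17850, AT1G24240, AT1G22040, AT1G76050, AT2G46190 and AT3G17950 among them (adjusted p of 0.066 to 0.225). Averaging 1 and 4, 2 and 5, and 3 and 6 ended 7, with AT1G17850, AT1G22040, AT1G76050 and AT3G17950 among them (adjusted p of 0.053 to 0.116). The direction of the 24 genes named above did not turn under any of the other settings that measured them, at most 33 per gene. This was largely fixed by their choice, as large changes with all 6 toc75 arrays on the same side of the WT mean. Averaging or blocking also leaves a log2 fold change as it was, so the stable direction is no further support.

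The second question was whether genes of the chloroplast and of linked metabolism shifted. Of 20 gene lists with 366 loci, 10 lists had measured members, 18 features in all. Against 25.7% of all 3439 features, 2 of these 18 changed, a difference that was not tested. With the values as deposited 5 passed, 1 higher and 4 lower in toc75, and 5 passed when centred on the median and 5 with a constant per array, all higher; PRPL29, at the floor on all arrays but 1, is among those that passed when centred. AT3G13120 (PRPS10, a plastid ribosomal protein) rose by 0.86 ± 0.25 on the log2 scale (SE, n = 6 per group, limma adjusted p = 0.025). AT3G58610 (KARI, ketol-acid reductoisomerase of branched-chain amino acid synthesis) rose by 0.36 ± 0.09 (limma adjusted p = 0.016). Both lay lower in toc75 with the values as deposited, at -0.10 and -0.18, without passing there. Both also lost their calls with consecutive numbers averaged (adjusted p = 0.057 and 0.112) or as a random block (adjusted p = 0.154 and 0.074). PRPS10 did not pass when centred on the median (0.43, adjusted p = 0.255), with cyclic loess (0.40, adjusted p = 0.317) or without toc75 numbers 3 and 4 (adjusted p = 0.063). KARI did not pass with numbers 1 and 4, 2 and 5, and 3 and 6 averaged (adjusted p = 0.068). With a pseudocount PRPS10 was at 0.32 and KARI at 0.22. KARI was at 0.19 for numbers 1 and 2 alone and 0.63 for numbers 3 and 4 alone, without passing. PRPS10 lost its call without WT replicate 2, 3, 4 or 5, with adjusted p of 0.053 to 0.057.

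The 6 measured photosynthesis genes of the lists fixed in advance did not pass the test. PSAN of photosystem I had a log2 fold change of 0.34 ± 0.21 (SE). PSBY and PSBW of photosystem II had values of -0.29 ± 0.12 and -0.0047 ± 0.085. The antenna gene LHCB1.5 had -0.23 ± 0.08, with a limma adjusted p of 0.070. The envelope transporter gene XPT had -0.25 ± 0.11 (limma adjusted p = 0.131). LHCB1.5, XPT and KARI were each the sole measured member of their list, so that a count adjusted over the list alone would carry no adjustment. The Calvin cycle genes PRK and SBPASE had -0.25 ± 0.19 and -0.21 ± 0.17. CHLP and CHLM of chlorophyll synthesis had 0.07 ± 0.08 and -0.18 ± 0.24. Some of these genes passed under another setting. PSBW was higher in toc75 as deposited (0.26, adjusted p = 0.028), centred on the median (0.78, adjusted p = 9.36e-05) and with a constant per array (0.26, adjusted p = 0.048). PSAN was higher when centred (1.004, adjusted p = 0.0026) and with a constant per array (0.52, adjusted p = 0.042) and for numbers 3 and 4 alone (0.94, adjusted p = 0.023), and CHLP when centred (0.59, adjusted p = 0.00060). PSBY was lower for numbers 1 and 2 alone (-0.65, adjusted p = 0.040). LHCB1.5 was lower with cyclic loess (-0.42, adjusted p = 0.013), without toc75 replicate 3 (adjusted p = 0.038) or 4 (adjusted p = 0.043) or both (adjusted p = 0.014), and for numbers 1 and 2 alone (-0.49, adjusted p = 0.015). SBPASE and XPT were lower as deposited (-0.52 and -0.50, adjusted p = 0.027 and 0.018), SBPASE also without toc75 replicate 6 (-0.35, adjusted p = 0.048) and XPT without toc75 replicate 2 (-0.32, adjusted p = 0.035) or for numbers 3 and 4 alone (-0.66, adjusted p = 0.035). The sign of PSAN, PSBY, PSBW, LHCB1.5, PRK, SBPASE, CHLP and XPT turned under at least 1 other scaling or subset of arrays.

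Of the lists fixed in advance, plastid ribosomal proteins were the only one with at least 5 measured members. Of its 6 members 1 rose and 5 did not pass, and 1 passed when adjusted over the list alone. PRPS6 had a log2 fold change of 0.74 ± 0.26 (SE, limma adjusted p = 0.061) and was at the floor on all 6 WT arrays. It passed in 10 of 31 other settings, among them zeros missing (1.23, adjusted p = 0.0083), a constant per array (0.74, adjusted p = 0.0086), array weights (adjusted p = 0.026) and the fits without toc75 replicate 1 (0.92, adjusted p = 0.017) or 4 (0.53, adjusted p = 0.029). PRPL17 had -0.26 ± 0.16, and passed as deposited (-0.47, adjusted p = 0.016), without numbers 5 and 6 (-0.33, adjusted p = 0.028) and for numbers 1 and 2 alone (-0.52, adjusted p = 0.017). PRPL29 was at the floor on all 6 WT arrays and on 5 of the 6 toc75 arrays, so its change cannot be measured here. No shift of the list against the other features was detected (camera adjusted p = 0.799 with a preset correlation, adjusted p = 0.796 with an estimated correlation). The estimated correlation between its 6 members was 0.32, and the power for such a list was not assessed, so a shift is not excluded. The mean log2 fold change of the list, which includes PRPS6 and PRPL29, was 0.34. Relative to other features it was 0.11 without toc75 replicate 4, 0.13 with a pseudocount, and turned to -0.13 without the dimmest 25% of features and -0.18 with features above the floor only. Among single members of other lists, PRXIIE of the antioxidant list had -0.30 ± 0.24 and FATB of fatty acid synthesis had 0.35 ± 0.43, and neither passed.

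**Figure D3:**
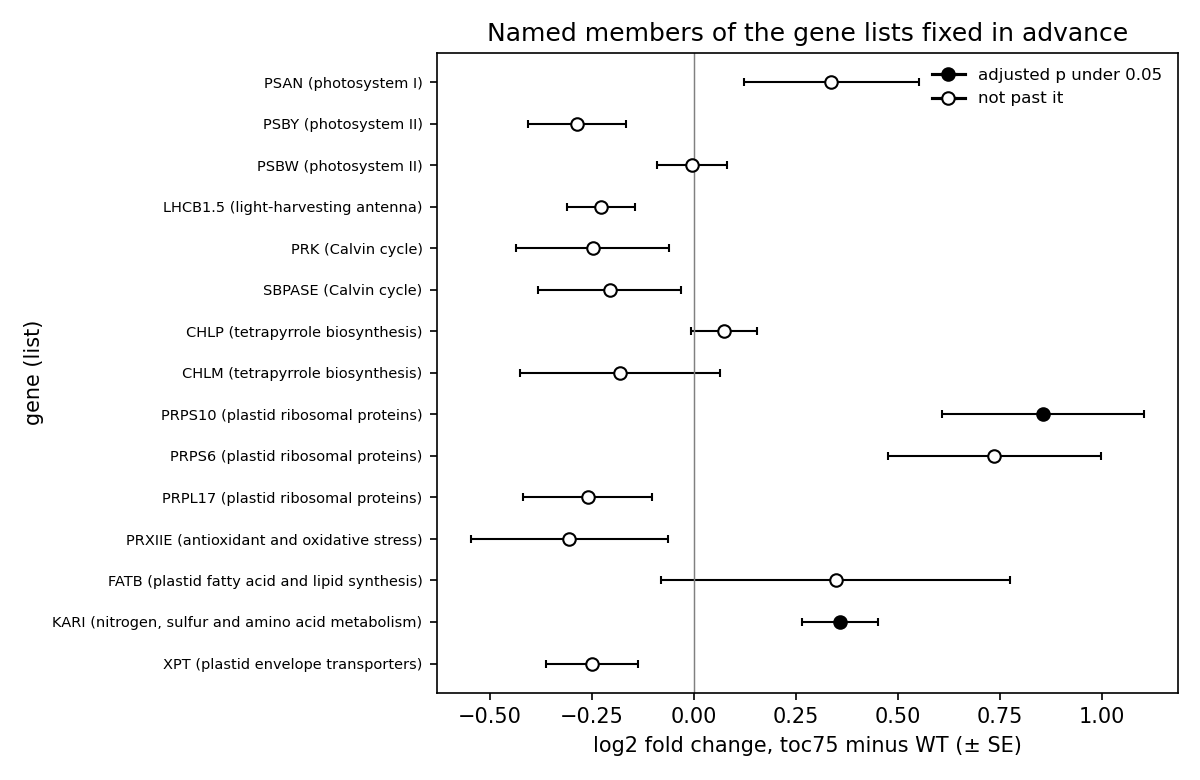
Log2 fold change, toc75 minus WT, with its SE (x axis) for the named members of the gene lists fixed in advance (y axis, list in brackets), from 6 arrays per group; filled circles passed an adjusted p under 0.05. PRPS10 at 0.86 and KARI at 0.36 passed, and the sign of both turned with the values as deposited; PRPL29, above the floor on 1 array only, is left out.

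The targeted gene could not be used to check the labels. Of the TOC75 family, 0 members were measured by a feature with a single named gene. The protein import list, photorespiration, starch metabolism, carotenoid synthesis, electron transport, plastid chaperones, non-green plastid markers, senescence and defence markers, and cytosolic reference genes likewise had 0 such features. These genes were not analysed here.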

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

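The tests below were set before the values were seen. In 5 of 116 groups of 6 arrays (2 groups for each of 55 named features and 3 array measures), 1 array lay far from the others; chance alone marks about 1 group in 20 (Dixon's ratio at its 95% critical value). AT1G17850 was at -0.41 (log2) on toc75 replicate 4, against -2.75 to -1.88 on the other toc75 arrays; without this array its log2 fold change was 0.85 against 1.18. GLX2-1 (AT2G43430) was at the floor of -3.80 on toc75 replicate 4, against -2.57 to -2.02 on the others. PRPL29 (AT5G65220) was at -1.51 on toc75 replicate 4 and at the floor on the other 5 toc75 arrays. NDHN (AT5G58260) was at -1.08 on toc75 replicate 2, against -0.48 to -0.29 on the others. AT3G11960 was at -3.68 on WT replicate 1, and its other WT arrays were all at the floor, which makes any value above it stand apart.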

How the results depend on the processing

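Subsets of array numbers, the constant per array and averaging combined with the block were chosen after seeing the data. The count of 884 features stayed within 1.5 times under most settings and ran from 761 to 901 with each array left out. It was 1595 with values as deposited, 1370 with a constant per array, 529 at an adjusted p under 0.01, 526 with at least 1.5-fold, 584 with consecutive numbers as a random block, 325 with consecutive numbers averaged, 0 with these averages and a replicate block, 496 for numbers 3 and 4 alone and 448 for numbers 5 and 6 alone. The replicate block gave 1131, of which 825 were shared with the 884 and 0 had the opposite sign; among named genes it ended the call of AT3G17950 and no other. The share higher in toc75 (51.0%, binomial interval 47.7 to 54.4%) was 11.3% as deposited, 69.3% centred on the median, 69.5% with a constant per array, 47.3% with cyclic loess, 56% with zeros missing and 54.6% with only zeros at the floor, and 50.2 to 52.0% with each array left out. The binomial interval treats features as independent, which they are not shown to be. Quantile normalization also held the median log2 fold change of all features near 0, which favours an even split. Without numbers 5 and 6 the count was 869, and without toc75 numbers 3 and 4 it was 854. Of 33 named calls, 7 were lost with numbers 1 and 4, 2 and 5, and 3 and 6 averaged, all 33 with consecutive averages and a replicate block, and 13, 16 and 19 for numbers 1 and 2, 3 and 4, and 5 and 6 alone. Of 22 named genes that did not pass, 17 passed under at least 1 other setting. The causes were not tested, except that stricter thresholds lower a count by construction. Averages with a block, and fits on 2 arrays per group, also leave few degrees of freedom to estimate the spread. Calls lost there do not show that the changes are absent.

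No list passed in camera under any setting; fry was rerun with the replicate block only. Relative to other features, the plastid ribosomal list turned from 0.34 to -0.13 without the dimmest 25% of features and -0.18 with features above the floor only (0.11 to 0.41 with each array left out). The photosystem and NDH list turned from -0.060 to 0.18 as deposited, 0.18 centred, 0.0083 without the dimmest 25% of features and 0.078 for numbers 3 and 4 alone (-0.090 to -0.027). The Calvin cycle and redox list turned from -0.098 to 0.030 for numbers 3 and 4 alone (-0.13 to -0.071). The developmental list turned from -0.012 to 0.019 with the pseudocount, 0.00097 without numbers 5 and 6, 0.0061 without toc75 numbers 3 and 4, 0.079 for numbers 1 and 2 alone and 0.050 with a constant per array (-0.041 to 0.024). The organelle RNA list ran from 0.20 to 0.29.

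These log2 fold changes turned. As deposited: PSBW (AT2G30570) 0.26, PRPS10 (AT3G13120) -0.096, FATB (AT1G08510) -0.14, KARI (AT3G58610) -0.18, CCS1 (AT1G49380) -0.32, CCS (AT1G12520) -0.36, OTP70 (AT4G25270) -0.0077, OTP85 (AT2G02980) -0.41, PAC (AT2G48120) -0.21 and SAP (AT5G35770) -0.31. Centred on the median: PSBY (AT1G67740) 0.29, PSBW 0.78, LHCB1.5 (AT2G34420) 0.37, PRK (AT1G32060) 0.13, SBPASE (AT3G55800) 0.00027, PRPL17 (AT3G54210) 0.053, PRXIIE (AT3G52960) 0.13 and XPT (AT5G17630) 0.020. Numbers 1 and 2 alone: PSAN (AT5G64040) -0.46, PSBW 0.19, CHLP (AT1G74470) -0.10, XPT 0.071 and OTP70 -0.022. Numbers 3 and 4 alone: PSBY 0.068, LHCB1.5 0.023, PRK 0.041 and OTP85 -0.31. Numbers 5 and 6 alone: SAP -0.34. PSBW was also 0.021 with array weights, 0.10 without numbers 5 and 6, 0.057 without toc75 numbers 3 and 4 and 0.26 with a constant per array (-0.050 to 0.038 with each array left out). With Spearman correlations the mean was 0.863 within toc75 and 0.861 between groups, against 0.882 and 0.884 with Pearson, and the pairing of consecutive numbers ranked 1 in toc75 in place of 3. The random block could not enter camera and was not run for lists, and the TOC75 family had no feature to rerun. Signal over background was not analysed here.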

Other observations

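The 4 lists in the first 2 paragraphs were chosen from the names of measured genes. The tests of a constant offset, of a scale factor, of bright features as the whole gap and of consecutive numbers, and averaging combined with a block, were chosen only after the results were seen.

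Among 9 measured genes of the Calvin cycle, chlorophyll synthesis and stromal redox control, 2 rose, 2 fell and 5 did not pass. NADP-MDH (AT5G58330), the stromal malate dehydrogenase, rose by 0.75 ± 0.12 on the log2 scale (SE, n = 6 per group, limma adjusted p = 0.00083), and by 1.34 when centred on the median; it was at 0.48 for numbers 3 and 4 alone. CCS (AT1G12520), the copper chaperone of superoxide dismutase, rose by 0.69 ± 0.15 (limma adjusted p = 0.0063), but lay at -0.36 with the values as deposited, and did not pass when centred on the median (0.16, adjusted p = 0.481) or with cyclic loess (0.10, adjusted p = 0.699). Sulfiredoxin SRX (AT1G31170) fell by 0.98 ± 0.28 and the thioredoxin reductase NTRC (AT2G41680) by 0.48 ± 0.14 (limma adjusted p = 0.023 and 0.030). SRX lost its call without WT replicate 1 (adjusted p = 0.051), and NTRC lost it in 5 of the 12 fits that left out 1 array, with adjusted p of up to 0.067. SRX lay at -1.69 as deposited and -0.47 with a constant per array, and NTRC at -0.88 as deposited and -0.36 when centred, without passing there (adjusted p = 0.084). NTRC did not pass without numbers 5 and 6 (adjusted p = 0.122) or without toc75 numbers 3 and 4 (adjusted p = 0.106). With a pseudocount CCS was at 0.24 and SRX at -0.45, and for numbers 5 and 6 alone CCS was at 0.21. With consecutive numbers as a random block SRX and NTRC did not pass (adjusted p = 0.061 and 0.091), nor NTRC with numbers 1 and 4, 2 and 5, and 3 and 6 averaged (adjusted p = 0.082). With consecutive numbers averaged none of the 4 passed (adjusted p = 0.059 for NADP-MDH, 0.057 for CCS, 0.163 for SRX and 0.173 for NTRC). The fry mixed adjusted p of the list was 9.19e-05, a test against no change and not against other features, of which 25.7% passed. No shift of the list in 1 direction against other features was detected (camera adjusted p = 0.799, and adjusted p = 0.796 with an estimated correlation).

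Of 13 measured photosystem, NDH and cytochrome subunits and assembly factors, 1 rose, 1 fell and 11 did not pass, and 4 passed with the array number as a block. CRR41 (AT1G51100), an assembly factor of the chloroplast NDH complex, rose by 0.51 ± 0.09, and NDHN (AT5G58260), a subunit of that complex, fell by 0.53 ± 0.12 (SE, limma adjusted p = 0.0018 and 0.0076). CRR41 was at 0.063 with the values as deposited (adjusted p = 0.689). NDHN was at -0.81 there and at -0.29 when centred on the median (adjusted p = 0.134). With consecutive numbers averaged both lost their call (adjusted p = 0.051 and 0.059), and with these numbers as a random block NDHN did (adjusted p = 0.055). CCS1 had a log2 fold change of 0.44 ± 0.18 and did not pass, but passed with a constant per array (0.48, adjusted p = 0.027). Of the 13, 5 were higher and 1 lower when centred on the median, and 2 were higher and 3 lower as deposited. The fry mixed adjusted p was 0.0038, again against no change. In the main fit the 2 calls among 13 are a smaller share than the 25.7% of all features. This difference was not tested, and it turned when centred on the median. Of 7 genes of organelle RNA processing 1 rose, MTERF9 (AT5G55580), by 0.96 ± 0.25 (limma adjusted p = 0.015), with its call lost without numbers 5 and 6 (adjusted p = 0.095), with consecutive numbers as a random block (adjusted p = 0.110) and with numbers 1 and 4, 2 and 5, and 3 and 6 averaged (adjusted p = 0.074); OTP70, OTP85 and PAC did not pass, although OTP70 did when centred on the median (0.52, adjusted p = 0.013) and for numbers 3 and 4 alone (0.34, adjusted p = 0.045), and OTP85 with a constant per array (0.44, adjusted p = 0.040). With the array number as a block the fry mixed adjusted p of this list went from 0.398 to 0.00027. Of 10 developmental and transcriptional regulators 0 passed (0 in limma at an unadjusted p under 0.05), the smallest p being those of TCP15, SPL, SAP and AGL103. With the values as deposited 6 of the 10 were lower, with TCP15 at -1.18 (adjusted p = 0.00038) and SPL at -0.97 (adjusted p = 0.0049). TCP15 also passed when centred on the median (-0.66, adjusted p = 0.0095), without toc75 replicate 5 (adjusted p = 0.0497) and without numbers 5 and 6 (adjusted p = 0.0097). SAP passed with a constant per array (0.65, adjusted p = 0.015), where 3 of the 10 were higher, and without numbers 5 and 6 (1.02, adjusted p = 0.045), as did AGL103 there (0.45, adjusted p = 0.038). SAP also passed for numbers 1 and 2 alone (0.66, adjusted p = 0.026) and for numbers 3 and 4 alone (1.37, adjusted p = 0.048). The camera adjusted p was 0.799 for each of these 3 lists. The shares of calls in the organelle RNA and developmental lists were not tested against the 25.7% either.

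If the 12 arrays are independent, the splits below argue against chance division of the arrays for the count of 884 features. Same-numbered arrays deviated together and consecutive numbers may share RNA, so this independence is not shown. Splits that mix the groups also carry the difference between them as scatter, which lowers their counts. Of 100 splits of the 12 arrays into 6 and 6, drawn from 462 with the real one included, 1 gave as many, and the highest of the others gave 0. Of the 32 splits that part all 6 same-number pairs, 1 gave as many, and the highest of the others gave 1; in those others some pairs had their WT and toc75 arrays exchanged. With consecutive numbers averaged, the 6 averages have 10 splits into 3 and 3, too few for a share under 0.05; the real one gave 325 and the highest of the others 0.

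The toc75 arrays had a lower median by 0.52 on the log2 scale. Rescaling without the brightest 1% of features left 0.649 of this gap (mean of 6 same-number pairs, SE 0.033). The test set in advance, of bright features as a cause, could not decide, because this value lay between its bounds. The share left argues only against a few bright features as the whole cause, by a rule chosen after the value was seen. A part may come from them. The difference between WT and toc75 at the 75th percentile was 1.37 times that at the 25th (SE 0.108). A single scale factor would give the ratio of the percentiles themselves, 3.23 to 3.29 on WT arrays, and the observed 1.37 lay below it. Array means lay between 0.933 and 1.04, so such a factor may have been removed before deposit. The outcome was then likely in advance, and it says nothing about a factor in the unscaled intensities. For numbers 1 to 6 the ratio was 1.04, 1.08, 1.48, 1.34, 1.60 and 1.67, so consecutive numbers lay close. Both SEs take the 6 pairs as independent and may be too small. A constant lower offset, such as a background subtracted more strongly, stays open at this value of 1.37, because 2 SE reach past the bound of 1.5 set for it. A lower level of many transcripts in the mutant also stays open, untested.

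Arrays of toc75 scattered more than WT arrays, with correlations of log2 values averaging 0.882 within toc75, 0.960 within WT and 0.884 between groups. The median ratio of SDs, toc75 over WT, was 1.49 over 2556 features above the floor. In the brightest 25% it was 1.16 (95% bootstrap interval over features 1.104 to 1.22, which treats features as independent), narrowly past the bound of 1.1. This argues against nearness to the floor in the scaled values as the whole cause, and the smaller ratio leaves room for a part. After scaling, every array held 373 features at the floor, so a group difference in their number could not be tested. Whether scaling the dimmer deposited toc75 values added scatter was not tested. Leaving out each toc75 array in turn gave at least 1.41, so a single array does not account for it. Variation between mutant plants stays open, untested.

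Consecutive array numbers may mark arrays that share RNA or a hybridisation; the consensus correlation of such pairs over all features, from limma, was 0.458. Among the 15 ways to pair 6 arrays, the pairing 1 with 2, 3 with 4 and 5 with 6 had the highest mean correlation of deviations in WT (0.38) and ranked 3 in toc75 (-0.11), and with Spearman correlations it ranked 1 in both groups. Deviations from a mean of 6 arrays correlate at -0.2 when nothing is shared; toc75 arrays 3 and 4 lay below this at -0.32 with Pearson and above it at -0.024 with Spearman, and the other consecutive pairs lay above it. On the second principal component of the log2 values, consecutive WT arrays lay together, at -11.0 and -10.5, -6.0 and -5.9, and 10.5 and 11.3. The toc75 arrays lay at -13.9 and -12.15, -0.617 and -3.99, and 21.6 and 20.7 there. On the third, toc75 arrays 3 and 4 lay apart, at 24.8 and -22.9. On the fourth, toc75 arrays 1 and 2 did, at -23.1 and 4.8. These values do not settle whether the numbers mark repeated reads or shared RNA. The ranking in toc75 and the place of its arrays 3 and 4 turned with the kind of correlation. If the numbers did mark repeats, each group would hold 3 samples, for which averaging left 325 calls. Averaging with the block, which follows the pairing of numbers across groups, left 0, with few degrees of freedom.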
